A study of Mus musculus with 4 samples.

How the data were processed

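The data are RNA-seq counts from 4 pull-downs of astrocyte ribosomes from mouse brain, 2 labelled cuprizone and 2 labelled mock. Per the labels' protocols, the mice carried a Cre recombinase under the GFAP promoter and 1 Rpl22 allele that gains an HA tag after recombination, so that an antibody against HA pulls down ribosomes of cells in which Cre was active, together with the RNA bound to them. The pulled-down RNA was purified on columns, samples with an RNA integrity number above 8 were kept, and libraries were made with a low-input kit that selects polyadenylated RNA, per the labels. The sample labels place all 4 libraries in batch 1 and at 3 weeks. The design text of the series instead describes collection at 5, 5.5 and 7 weeks, and the mismatch could not be settled from the sources used here, so the time is given as the sample labels state it. Libraries of other times, and RNA from the tissue before the pull-down, were not analysed here.

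The authors deposited 1 table per library with raw counts per Ensembl gene, not normalized. Per the submitters' processing notes, the steps before deposit used FastQC 0.11.9, STAR 2.5.4b and featureCounts 1.6.0 with the mouse build GRCm38, also named mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes can therefore have been dropped or shared, which matters for the MHC class I genes, the metallothioneins and the mitochondrially encoded genes, which have nuclear copies. Each table listed 55471 genes, all values were whole numbers, and no row stood for unassigned reads. Symbols were matched for 55144 ids, and the other 327 held at most 0.023% of the counts of any library. Coordinates and gene types come from GENCODE M21, which is on GRCm38 and may not be the release the authors counted with; 55230 ids had a record in it.

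Library totals were 21834814 counts in cuprizone replicate 1, 23822620 in cuprizone replicate 2, 22109536 in mock replicate 1 and 21209517 in mock replicate 2, a range of 1.12-fold. A gene with a count of 0 could still have had a level of up to 0.126 to 0.141 CPM, the value of 3 counts in the largest and the smallest library. That limit covers counting error only, since reads without molecular identifiers are not independent molecules. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.960 within the cuprizone pair, 0.969 within the mock pair and 0.947 to 0.958 across groups. A chi-square over genes with at least 20 counts gave 56.5 per degree of freedom within the cuprizone pair and 35.1 within the mock pair, so neither pair differed by as little as sampling noise. The labels call the libraries biological replicates and do not say whether 1 library came from 1 animal or from several, so the p-values measure the spread between these libraries.

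Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, glmQLFit with robust estimation and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block or covariate entered, and 15816 genes were tested. Folds are cuprizone over mock on the log2 scale, and the SE of a log2 fold is its size divided by the square root of its F statistic. CPM values are scaled with the TMM factors, which ran from 0.974 to 1.031. The design had been written without naming which of the package's 2 ways of estimating quasi-likelihood dispersions to use. The default of the installed version was taken after the counts of calls under both had been seen, and the other, bias-adjusted way called 51 genes instead of 13.

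A total of 35 gene lists was written before the data were examined, of which 32 had the minimum of 5 tested members. They were tested with camera from limma 3.58.1 on the edgeR fit, with the preset correlation between genes of 0.01, 2-sided and adjusted over the lists. Camera asks whether a list's genes lie lower or higher than the other genes. For each list the calls over all genes and the calls with adjusted p over the list alone were counted. Lists for 11 other cell types were included, because a pull-down can carry RNA of other cells, and their summed counts were also taken as a share of each library. Named genes followed a rule written beforehand: up to 10 rises and 10 falls of the largest size among called genes with a mean CPM of at least 5 and groups that did not overlap, at most 3 called members of each list or else its most abundant member, and always Gfap and Rpl22. A gene that the rule named is not reported here. Members added as examples for a list were chosen after their values were seen: Slc1a2, Slc1a3, Kcnj16, Mlc1, Vim, Serpina3n, Cyp51, Sc5d, Clu, Abcg1, Gsr, Hspa5, Herpud1, H2-K1, Bst2, Ncan, Lamp1, Ctsl, Arc, Npas4, Mbp, Ermn, C1qb, Syt1, Thy1, Rbfox3, Mt3 and Asns.

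Alternatives fixed beforehand were RLE, upper-quartile and library-size scaling, TMM factors from a reduced gene set, DESeq2 1.42.0, limma-voom, no low-count filter, a mean CPM of at least 1, the replicate number as a block, a test against a 1.5-fold change, camera with an estimated correlation, the rotation test fry, and leaving out each library in turn. Chosen after seeing the data were the bias-adjusted estimation and a run without mitochondrially encoded genes. The gene test was tested on simulated data drawn from the means, library sizes and dispersions of these libraries. It recovered 21 of 67 genes changed 2-fold (31.3%), 45 of 67 changed 4-fold (67.2%) and 59 of 66 changed 16-fold (89.4%). It also called 12 unchanged genes, with 15033 genes run, the changed ones included. The 12 false calls are to be read against the recovered genes, not against all genes run. In simulated sets of 15 genes, a list lowered 2-fold was called by camera with the preset correlation and not with an estimated one, and 0 of 20 unshifted lists were called. The simulated genes were drawn independently of each other. The sets therefore cannot show how often camera with the preset correlation calls unshifted lists of correlated genes. For the closing section, the protein of each gene was translated from its longest GENCODE coding sequence with Python 3.11.15 and placed in 1 of 2 classes by hydrophobicity. A protein counted as having a membrane or signal segment if a window of 19 residues averaged at least 1.6 on the Kyte-Doolittle scale, or if a window of 9 within the first 30 residues averaged at least 2.2. Of 36 genes of known class, 32 were placed correctly. The errors all went 1 way: S100b, Pkm, Camk2a and Hsp90ab1, known to lack a segment, were placed with the genes that have one.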

Results

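Cuprizone is a copper chelator which, mixed into chow, kills oligodendrocytes and strips myelin from the corpus callosum, the white matter tract between the hemispheres. The series' design text describes male mice of 8 to 9 weeks fed 0.2% cuprizone by weight, matched mice on normal chow, and pull-downs from micro-dissected corpus callosum. RNA pulled down with tagged ribosomes, aimed at those of astrocytes, was sequenced from 2 cuprizone and 2 mock samples, all labelled 3 weeks. The libraries held between 21209517 and 23822620 counts, and between 19496 and 19996 genes had at least 1 count in a library. The comparison asks how the pulled-down RNA differed between mice on cuprizone and mice on normal chow. All 4 libraries were labelled batch 1, so diet did not coincide with the labelled batch.

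In the cuprizone libraries, 5 genes rose and 8 fell. The rises were in Sptan1 and Sptbn1, which encode the alpha and beta spectrins of the membrane skeleton, and in the RNAs Snhg11, Meg3 and Malat1, of which Meg3 and Malat1 are long non-coding RNAs found mainly in the nucleus. The falls were in 5 genes of the mitochondrial genome (mt-Rnr2, mt-Nd4, mt-Cytb, mt-Co1 and mt-Nd1), in Apoe, the main lipid carrier protein secreted by astrocytes, in Cpe, a peptide-processing enzyme of secretory vesicles, and in Sparcl1, a secreted matrix protein of astrocytes. Sptan1 stood at 912 CPM ± 105 (SD, n = 2) in cuprizone and 112 ± 1.02 (n = 2) in mock libraries, a log2 fold of 3.02 (SE 0.16). Apoe stood at 2439 CPM ± 24.0 (n = 2) against 6806 ± 335 (n = 2), a log2 fold of -1.48 (SE 0.11). The edgeR quasi-likelihood test gave adjusted p = 0.00528 for Sptan1 and 0.0176 for Apoe.

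The log2 folds of the other rises were 3.13 for Snhg11 (SE 0.19), 2.27 for Meg3 (SE 0.17), 1.96 for Malat1 (SE 0.17) and 1.87 for Sptbn1 (SE 0.18). Sptbn1 went from 147 CPM ± 27.2 in mock to 535 ± 13.7 in cuprizone libraries, and Malat1 from 132 ± 18.1 to 514 ± 41.2 (SD, n = 2 each). Cpe fell from 3458 CPM ± 405 to 1228 ± 47.6 and Sparcl1 from 2442 ± 138 to 959 ± 30.7 (SD, n = 2 each), log2 folds of -1.49 (SE 0.13) and -1.35 (SE 0.12). Among the mitochondrial genes, mt-Co1, which encodes subunit 1 of cytochrome oxidase, fell from 133 CPM ± 7.54 to 6.99 ± 0.367 and the ribosomal RNA mt-Rnr2 from 115 ± 7.15 to 3.95 ± 1.84 (SD, n = 2 each). Reads from the mitochondrial genome made up 0.0033% and 0.0032% of counts in the cuprizone libraries and 0.0517% and 0.0503% in the mock libraries. On GRCm38, Sptan1 (ENSMUSG00000057738) spans 29965560 to 30031451 on chromosome 2, Sptbn1 (ENSMUSG00000020315) 30099395 to 30268175 on chromosome 11, Apoe (ENSMUSG00000002985) 19696109 to 19699188 on chromosome 7, Cpe (ENSMUSG00000037852) 64592542 to 64693054 on chromosome 8 and Sparcl1 (ENSMUSG00000029309) 104079111 to 104113733 on chromosome 5. All these counts are for whole genes and do not separate exons, introns or untranslated regions.

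The count of 13 depended on the libraries and the test. Without mock replicate 1, and likewise without mock replicate 2, the test called 2 rises and 3 falls, and the 5 genes called in both cases were Snhg11, Sptan1, mt-Rnr2, mt-Cytb and mt-Co1; without cuprizone replicate 1 it called 52 and 71, without cuprizone replicate 2 it called 9 and 17, and DESeq2 called 264 and 451. All 13 kept their direction wherever they were tested.

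**Figure D1:**
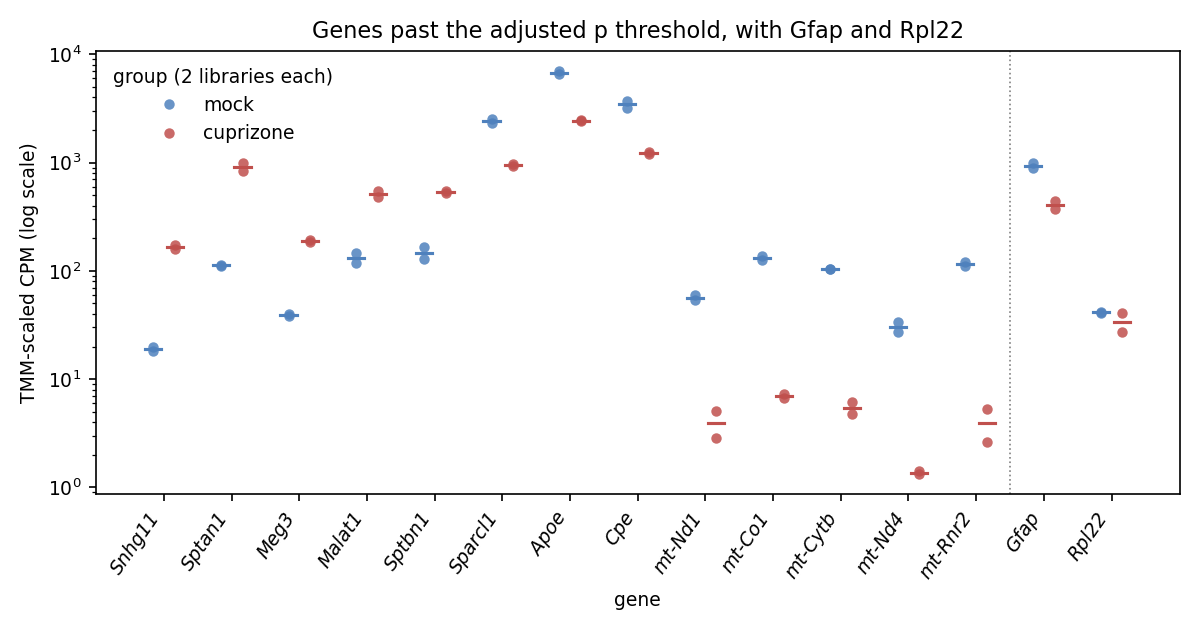
TMM-scaled CPM on a log axis of the 13 genes past the edgeR threshold, with Gfap and Rpl22 to the right of the dotted line. Each point is 1 library, blue for mock and red for cuprizone, each bar is the mean of 2 libraries, and in each of the 13 genes both cuprizone libraries lie on 1 side of both mock libraries.

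Gfap, whose promoter drives Cre and whose protein is the intermediate filament of reactive astrocytes, was not called: its log2 fold was -1.20 (SE 0.15), with 408 CPM ± 49.7 in cuprizone and 940 ± 69.3 in mock libraries (SD, n = 2 each). The edgeR adjusted p was 0.0838; it ran from 2.01e-10 with DESeq2 to 0.346 over the alternatives, 7 of which put Gfap past the threshold, and its log2 fold from -1.33 to -1.09. Rpl22, which carries the tag, had 34.0 CPM ± 9.87 against 41.4 ± 0.458 (SD, n = 2 each), a log2 fold of -0.29 (SE 0.28) and an edgeR adjusted p of 0.767. Gfap (ENSMUSG00000020932) lies at 102887336 to 102900912 on chromosome 11 and Rpl22 (ENSMUSG00000028936) at 152325742 to 152334071 on chromosome 4.

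Astrocyte markers as a list lay lower in the cuprizone libraries, with a median log2 fold of -0.55 over 17 genes. Over all genes edgeR called 0 of the 17, while 9 had an unadjusted p under 0.05, DESeq2 called 7 and limma-voom 2; 8 fell when adjusted over the list alone, and 16 had negative folds. The 18 genes of astrocyte transport and homeostasis had a median of -0.49; again edgeR called 0 over all genes (7 at an unadjusted p under 0.05, and 7 by DESeq2 and 1 by limma-voom after adjustment), 7 fell when adjusted over the list alone, and 7 of its genes are also in another of the lists. Slc1a2 and Slc1a3, the glutamate transporters of astrocytes, had log2 folds of -1.68 (SE 0.22) and -0.73 (SE 0.14), Kcnj16, a potassium channel subunit, -1.46 (SE 0.23), and Mlc1, a membrane protein of astrocyte endfeet, -1.31 (SE 0.20). Aldoc, a glycolytic enzyme, stood at -0.55 (SE 0.14), and Atp1b2, a sodium pump subunit, at -0.01 (SE 0.24). Only 9 of the 17 markers and 9 of the 18 transport genes were lower in both cuprizone than in both mock libraries. In the other members the groups overlapped. Camera gave adjusted p = 1.65e-08 for the markers and 4.92e-08 for transport with the preset correlation, and adjusted p = 0.326 for each with an estimated correlation. Without mock replicate 2 the median of the transport list was -0.22, and over the runs with 1 library left out it ran from -0.70 to -0.22.

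Genes of lysosomes, the endoplasmic reticulum and the extracellular matrix lay lower as well. In the list of phagocytosis and lysosome, 17 of 19 tested genes had negative folds and 8 fell when adjusted over the list alone, with a median log2 fold of -0.81. Lamp1, a protein of the lysosomal membrane, had -1.18 (SE 0.17), and the lysosomal proteases Ctsb and Ctsl -0.81 (SE 0.13) and -1.09 (SE 0.18). Of 14 ER chaperones and related genes, 8 fell and 1 rose when adjusted over the list alone, with a median of -0.68. The chaperones Canx and Hspa5 stood at -0.99 (SE 0.16) and -0.81 (SE 0.19), and Herpud1, which serves the disposal of misfolded ER proteins, at 0.53 (SE 0.19). Of 18 matrix genes, Sparcl1 was called over all genes and 3 fell when adjusted over the list alone, with a median of -0.72; Ncan, a secreted proteoglycan, had -1.41 (SE 0.22). The matrix median was -0.45 without cuprizone replicate 1 and -0.34 without mock replicate 2, and fibroblast genes took 0.0008% ± 0.0005 of counts in cuprizone and 0.0030% ± 0.0013 in mock libraries (SD, n = 2 each). Camera gave adjusted p = 5.67e-11 for lysosomes, 9.79e-06 for ER chaperones and 0.000198 for matrix, and adjusted p = 0.273, 0.326 and 0.345 with an estimated correlation. The lysosome list took 0.133% ± 0.0007 of counts in cuprizone and 0.227% ± 0.012 in mock libraries; the microglia list, whose cells are rich in lysosomal and MHC genes, took 0.0009% ± 0.0005 and 0.0045% ± 0.0011 (SD, n = 2 each).

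Both lipid lists lay lower too. Of 14 genes of lipid transport and cholesterol export, Apoe was called over all genes, and 4 fell and 1 rose when adjusted over the list alone, with a median log2 fold of -0.47. Clu, a secreted apolipoprotein, had -1.06 (SE 0.14), and Abcg1, a transporter that exports cholesterol, 0.66 (SE 0.18). Of 22 genes of cholesterol synthesis, 21 had negative folds and 2 fell when adjusted over the list alone, with a median of -0.43. The sterol enzymes Cyp51 and Sc5d stood at -0.98 (SE 0.21) and -0.89 (SE 0.18), and Hmgcs1, an early enzyme of the pathway, at -0.07 (SE 0.17). Camera gave adjusted p = 0.00029 for transport and 0.000203 for synthesis, and adjusted p = 0.326 and 0.423 with an estimated correlation.

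Genes that mark reactive astrocytes and immune responses mostly had negative folds. Of 13 pan-reactive genes, 9 could be tested, of which 2 fell and 1 rose when adjusted over the list alone, with a median log2 fold of -1.20. Serpina3n, a secreted protease inhibitor, had -1.68 (SE 0.35), whereas Vim, the filament vimentin, had 1.28 (SE 0.39), with 36.5 CPM ± 14.2 in cuprizone against 15.025 ± 4.56 in mock libraries (SD, n = 2 each). The list's call (camera adjusted p = 0.013, and adjusted p = 0.326 with an estimated correlation) was lost without cuprizone replicate 1, cuprizone replicate 2 or mock replicate 2, at adjusted p = 0.0555, 0.104 and 0.152; over all its alternatives the adjusted p ran from 0.00292 to 0.326. The A1-labelled list (median -0.57, camera adjusted p = 0.073), represented by H2-D1 at -1.52 (SE 0.31), and the A2-labelled list (median -0.53, 0.126), represented by S100a10 at 0.00 (SE 0.27), did not pass. The A1-labelled list passed without mock replicate 1 (adjusted p = 0.0091) and with library-size scaling (0.0475), in a range of 0.0091 to 0.423 over its alternatives, and its median ran from -1.11 without cuprizone replicate 2 to -0.34 without cuprizone replicate 1. The A2-labelled median ran from -1.19 without cuprizone replicate 1 to 0.06 without cuprizone replicate 2. In 10 tested genes of MHC class I presentation the median was -1.07 and 3 fell when adjusted over the list alone. B2m, the invariant light chain, had -1.14 (SE 0.16) and H2-K1 -1.25 (SE 0.28), and the list had a camera adjusted p of 7.22e-06, and adjusted p = 0.326 with an estimated correlation. The interferon list had a median of -0.80 over 17 genes, of which edgeR called 0 when adjusted over the list alone, 5 had an unadjusted p under 0.05 with a negative fold, and DESeq2 called 1 and limma-voom 0 over all genes; Bst2, an antiviral membrane protein, stood at -1.62 (SE 0.47) and Ifi27 at -0.08 (SE 0.22). Its camera adjusted p was 0.000396, and adjusted p = 0.423 with an estimated correlation, and its median was -1.29 without cuprizone replicate 2, -1.24 without mock replicate 1 and -0.16 without mock replicate 2.

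Complement (5 genes tested, median -0.53, camera adjusted p = 0.385), STAT3 and NF-kB signalling (13 genes, median 0.03, 0.765) and cytokines, chemokines and growth factors (15 genes, median -0.47, 0.0547) did not pass as lists. The cytokine list passed without cuprizone replicate 1 (adjusted p = 0.0263, median -0.81), without mock replicate 1 (0.0235), with library-size scaling (0.0475) and at a mean CPM of at least 1 (0.0218), in a range of 0.0218 to 0.345 over its alternatives. Cd59a, a complement inhibitor, had a log2 fold of -0.17 (SE 0.58), Stat3 of 0.28 (SE 0.20) and Il33, an alarmin, of 0.62 (SE 0.22). The complement median ran from -0.86 without cuprizone replicate 1 to -0.46 without cuprizone replicate 2, and the fold of Il33 from 0.89 to 0.28 without the same libraries. MHC class II had 4 tested genes, too few for the list test, all with negative folds, among them H2-DMa at -0.79 (SE 0.35). For STAT3 and NF-kB signalling and for the neuron, neuroblast, pericyte and cell cycle lists, the median, the mean and the direction of the test did not all have the same sign. Leaving out 1 library turned the sign of the median of the A2-labelled, STAT3 and NF-kB, cell cycle, oligodendrocyte, neuroblast, endothelial and ependymal lists.

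The mitochondrially encoded list had the lowest median of the 32 lists tested in the main fit, -3.83 over 7 genes, all 7 of which fell when adjusted over the list alone and 4 over all genes (mt-Rnr2, the fifth called gene, is not in the list). Camera gave adjusted p = 2.57e-50, and adjusted p = 0.13 with an estimated correlation. Without cuprizone replicate 2 its median was -4.19. That of the microglia and macrophage list was then fitted at -7.35, but rests on counts of 0 or near 0 in the remaining cuprizone library. These medians can therefore not be ranked. Nuclear genes of the respiratory chain had a median of -0.20 over 25 genes (camera adjusted p = 0.144), with Atp5b, a subunit of ATP synthase, at 0.12 (SE 0.13). The respiratory chain list passed without cuprizone replicate 1 (adjusted p = 0.0276, median -0.39, in a range of 0.0276 to 0.594 over its alternatives), and its median was -0.08 without cuprizone replicate 2 and -0.09 without mock replicate 1. The glycolysis list (18 genes, median 0.08, 0.636), the integrated stress response (19 genes, median 0.13, 0.638) and the NRF2 targets (17 genes, median 0.24, 0.136) did not pass. In the last, 15 of 17 genes had positive folds, among them Gsr, glutathione reductase, at 0.92 (SE 0.29), while the most abundant, Gstm1, a glutathione transferase, had -0.40 (SE 0.14). For the stress response, Psat1 and Asns, enzymes of serine and asparagine synthesis, stood at 0.13 (SE 0.15) and 0.37 (SE 0.17). The stress response median ran from 0.03 without mock replicate 1 to 0.32 without mock replicate 2. That of glycolysis ran from 0.03 without cuprizone replicate 2 to 0.12 without mock replicate 2. The NRF2 median ran from 0.14 without cuprizone replicate 2 to 0.35 without cuprizone replicate 1. Leaving out 1 library moved Psat1 from 0.03 to 0.27, Gstm1 from -0.52 to -0.26 and Atp5b from 0.0032 to 0.2178.

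Copper handling and metallothioneins, the list closest to the drug's chemistry, had a median log2 fold of -0.37 over 18 genes, of which 16 had negative folds. EdgeR called 0 of them when adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0 over all genes. The metal-binding metallothioneins Mt1 and Mt3 had -0.49 (SE 0.24) and -0.75 (SE 0.24). Its call (camera adjusted p = 0.0242, and adjusted p = 0.326 with an estimated correlation) was lost without mock replicate 1, at adjusted p = 0.0508, and the adjusted p ran from 0.0132 to 0.326 over its alternatives; the median was -0.64 without cuprizone replicate 1. Immediate early genes, which are switched on within minutes by stimulation, were the only one of the 32 lists that lay higher by camera with the preset correlation: 10 of 12 had positive folds, with a median of 0.45. EdgeR called 0 of them when adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0 over all genes. Npas4 had 1.65 (SE 0.50), Arc 0.48 (SE 0.15) and Egr1 0.18 (SE 0.14). Camera gave adjusted p = 0.00292, and adjusted p = 0.326 with an estimated correlation, and the list's median was 0.21 without mock replicate 2. The cell cycle list (19 genes, median -0.08) did not pass (camera adjusted p = 0.765), and Pcna, a replication clamp, stood at 0.22 (SE 0.18).

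**Figure D2:**
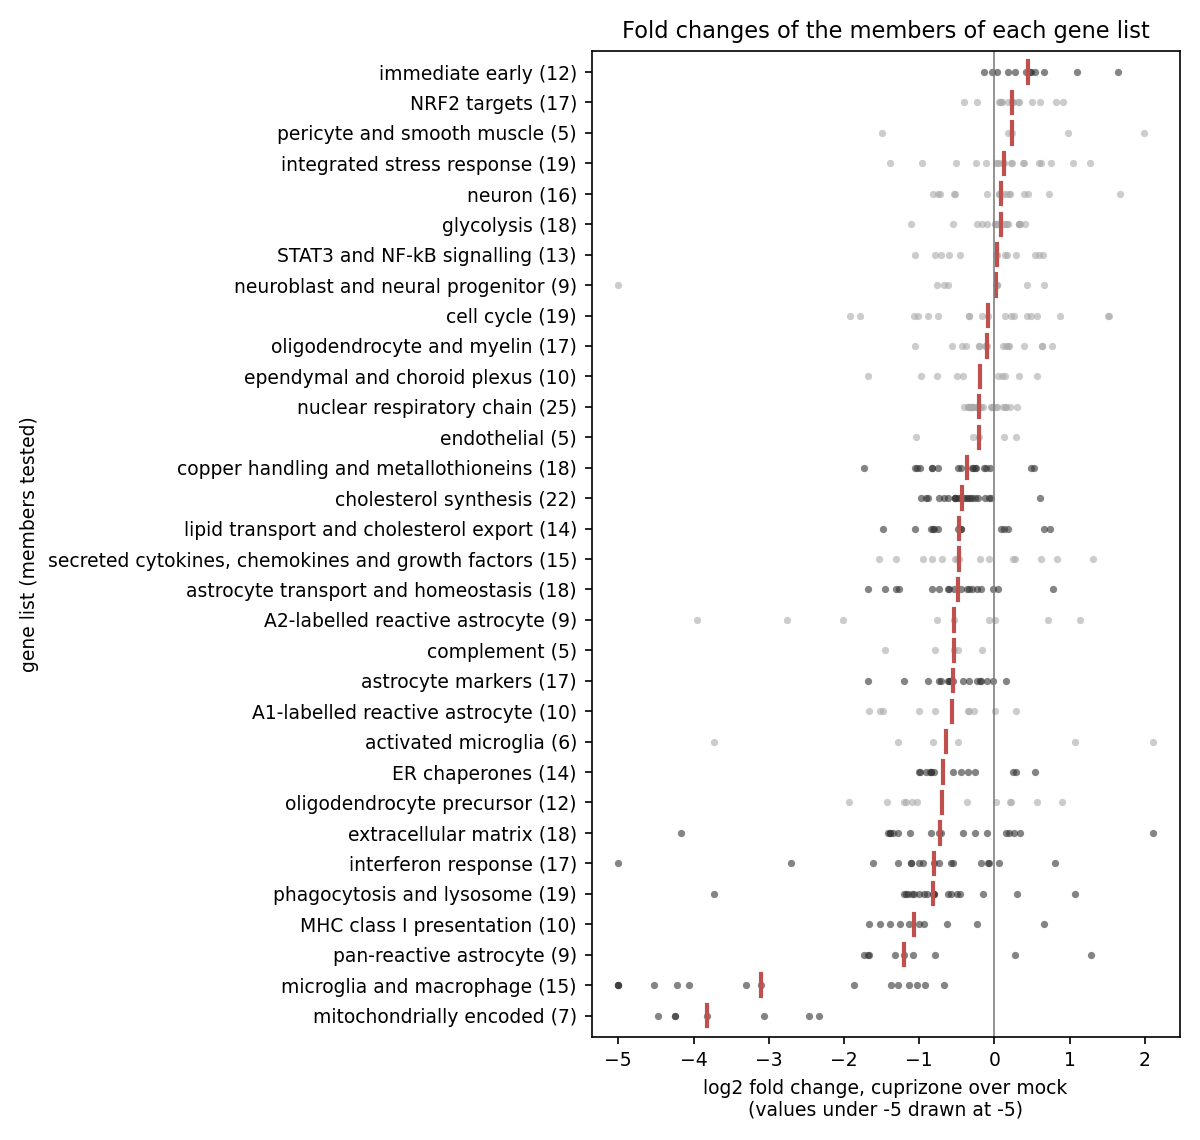
Log2 fold change, cuprizone over mock, of each tested gene in the 32 lists tested, with the number of tested members in brackets. Each point is 1 gene (values under -5 are drawn at -5), red bars are medians, and dark points mark the 14 lists past the camera threshold with the preset correlation, 13 of them lower and 1 higher. With an estimated correlation, 0 lists passed.

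Genes known from other cell types had counts in both groups. Neuron genes made up 1.77% ± 0.0194 of counts in cuprizone and 1.57% ± 0.0549 in mock libraries, and oligodendrocyte and myelin genes 1.44% ± 0.279 and 1.65% ± 0.172 (SD, n = 2 each), while the astrocyte markers made up 0.916% ± 0.106 and 1.30% ± 0.0192. Folds of genes that several cell types express can therefore not be assigned to astrocytes. Snap25, a synaptic protein of neurons, reached 9727 CPM ± 163 in cuprizone and 8507 ± 17.2 in mock libraries, a log2 fold of 0.19 (SE 0.10). Within the neuron list, Syt1 and Thy1, both anchored in membranes, had -0.52 (SE 0.14) and -0.82 (SE 0.18), and Rbfox3, a nuclear protein, 0.45 (SE 0.19). The list did not pass (median 0.09, camera adjusted p = 0.765), and 1 of its 16 genes fell when adjusted over the list alone. Its median ran from 0.04 without cuprizone replicate 2 to 0.18 without mock replicate 2.

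Myelin genes as a list did not pass. Mbp, myelin basic protein, stood at 2096 CPM ± 515 in cuprizone and 4370 ± 419 in mock libraries, a log2 fold of -1.06 (SE 0.19) with an edgeR adjusted p of 0.133. Ermn, a cytoskeletal protein of oligodendrocytes, had 0.63 (SE 0.16). The oligodendrocyte list had a median of -0.09 over 17 genes, 1 of which fell when adjusted over the list alone (camera adjusted p = 0.765). The precursor list had a median of -0.70 over 12 genes, of which 2 fell when adjusted over the list alone (camera adjusted p = 0.107). It passed without cuprizone replicate 2 (0.0257) and without mock replicate 1 (0.0268), and its median was -0.16 without cuprizone replicate 1 and -0.40 without mock replicate 2; over its alternatives the adjusted p ran from 0.0257 to 0.594. Its most abundant member Olig1 stood at 0.02 (SE 0.33).

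Microglia and macrophage genes were scarce in all libraries and scarcer in the cuprizone ones, at 0.0009% ± 0.0005 of counts against 0.0045% ± 0.0011 (SD, n = 2 each). All 15 tested genes had negative folds and 5 fell when adjusted over the list alone; 3 had a count of 0 in both cuprizone libraries, and the median log2 fold was -3.11 with these at their fitted values and also at a bound of 3 counts over the group. The complement gene C1qb had 0.249 CPM ± 0.29 in cuprizone and 5.90 ± 3.54 in mock libraries, and Ctss, a lysosomal protease of microglia, 0.557 ± 0.788 and 9.45 ± 1.79 (SD, n = 2 each). Camera gave adjusted p = 3.89e-06, and adjusted p = 0.326 with an estimated correlation. The list's fitted median was -7.35 without cuprizone replicate 2 and ran up to -2.16 when another library was left out. No bound was applied to these medians. The activated microglia list (6 genes, median -0.65, camera adjusted p = 0.61) with Lpl at -0.82 (SE 0.45), the neuroblast list (9 genes, 0.02, 0.366) with Tubb2b at -0.66 (SE 0.19), the endothelial list (5 genes, -0.20, 0.678) with Esam at -0.20 (SE 0.52), the pericyte list (5 genes, 0.24, 0.80) with Rgs5 at -1.50 (SE 0.46) and the ependymal list (10 genes, -0.19, 0.765) with Ttr at -1.68 (SE 1.29) did not pass. The fibroblast list had 4 tested genes, among them Dcn at -1.92 (SE 0.83), and the leukocyte list had 0, so neither could be tested as a list. Leaving out 1 library moved the medians of these lists. The activated microglia median ran from -1.55 without cuprizone replicate 1 to -0.28 without mock replicate 1. The endothelial median ran from -2.85 without cuprizone replicate 2 to 1.28 without mock replicate 2. The pericyte median ran from 0.10 without cuprizone replicate 2 to 0.80 without mock replicate 1. The neuroblast median ran from -0.60 without mock replicate 2 to 0.32 without mock replicate 1, and the ependymal median from -0.64 without cuprizone replicate 1 to 0.39 without mock replicate 1. The fold of Ttr ran from -5.35 without cuprizone replicate 2 to -0.08 without mock replicate 1. That of Dcn ran from -2.98 without cuprizone replicate 1 to -0.63 without mock replicate 1 and that of Lpl from -1.55 without cuprizone replicate 1 to -0.33 without cuprizone replicate 2. Those of Ctss and C1qb ran from -10.67 and -6.88 without cuprizone replicate 2 to -3.08 and -3.68 without cuprizone replicate 1. In cuprizone replicate 1 Ctss had 0 CPM and C1qb 0.044, under the 0.137 CPM that 3 counts make there. The folds of -10.67 and -6.88 therefore give a direction and not a size.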

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

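The bias-adjusted estimation and the run without mitochondrially encoded genes were chosen after the data had been seen; the other settings were fixed before the data were examined. Against 5 higher and 8 lower genes, RLE, upper-quartile, library-size and reduced-set TMM scaling each called the same 13 genes. DESeq2 called 264 higher and 451 lower, limma-voom 9 and 38, no low-count filter 45 and 146, a mean CPM of at least 1 gave 14 and 54, the bias-adjusted estimation 9 and 42, the test against a 1.5-fold change 3 and 4, and the run without mitochondrially encoded genes 4 and 3, the last partly because 5 called genes were left out. Leaving out 1 library gave 2 to 52 higher and 3 to 71 lower genes, where the lone library is assumed to vary like the other group; the fewest calls, 5, came without either mock library and the most without cuprizone replicate 1. The causes of these differences were not tested. All 13 genes kept their direction wherever tested, and Snhg11, Sptan1, mt-Rnr2, mt-Cytb and mt-Co1 stayed past the threshold under every setting that tested them. Same-numbered libraries did not deviate together (correlation 0.01 of their deviations from the group means), so the numbers were not taken as pairs. With the replicate number as a block, 5 higher and 5 lower genes were called, 8 of them among the 13, and the block changed no list call.

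For the lists, 13 lower and 1 higher became 0 and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05, and 1 (mitochondrially encoded) and 0 with fry, which tests whether a list moves at all and does not compare it with other genes. Of the other cell type lists, 1 was lower (microglia and macrophage), 0 with an estimated correlation or fry, and 1 to 3 when 1 library was left out. Over the other settings 12 to 17 lists were lower and 1 was higher. Of 1147 values of the 72 named genes under alternatives, 1034 kept their direction and their side of the threshold, 66 passed it newly, 29 no longer passed it and 18 changed sign, all of these in uncalled genes whose folds were close to 0. S100a10 had a log2 fold of -0.0001 with upper-quartile and with reduced-set TMM factors, -0.0169 with limma-voom, -0.0008 with a mean CPM of at least 1, -0.0083 with the replicate block and -0.003 with the bias-adjusted estimation, and Atp1b2 had 0.0555 with library-size scaling. Leaving out 1 library moved the log2 fold of S100a10 from -0.269 to 0.2266, of Atp1b2 from -0.4321 to 0.3093, of Hmgcs1 from -0.2554 to 0.1569, of Ifi27 from -0.3724 to 0.1581, of Cd59a from -0.6707 to 0.6692, of Olig1 from -0.4287 to 0.4669 and of Esam from -0.79 to 0.2122; the cause was not tested. With the sign kept, it moved Mt1 from -0.7323 to -0.1566, Mt3 from -1.0819 to -0.4859, Vim from 0.8169 to 1.6546, Rpl22 from -0.6191 to -0.0175, Stat3 from 0.1556 to 0.4484, Gsr from 0.5511 to 1.207, Asns from 0.2093 to 0.5184, Rbfox3 from 0.2218 to 0.734, H2-D1 from -1.8846 to -1.0072 and H2-DMa from -1.0965 to -0.3686. Depth was not varied; of the listed genes, 0 reached a mean of 5 CPM by library size in the microglia list, 1 each in the activated microglia, endothelial and pericyte lists and 2 in the fibroblast list, so folds of these genes rest on few counts.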

Other observations

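The tests of long non-coding RNA and of the astrocyte lists were chosen after those folds, or some of them, had been seen. After Malat1, Meg3 and Snhg11 had been seen to rise, they were set beside 5 RNAs known to stay in the nucleus. Snhg11 was taken as nuclear with them, although its gene type in GENCODE M21 is protein-coding and its place in the cell was not tested. Miat had a log2 fold of 0.85 and Kcnq1ot1 of 0.76, Neat1 of 1.09 and Rian of 0.41 with overlapping groups, and Mirg of 3.15 at a mean of 0.841 CPM. EdgeR called none of the 5.

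Neuron genes of different brain regions were compared, from lists written before their values were seen except where stated. Of 12 genes of cerebellar granule cells, 7 were higher in both cuprizone than in both mock libraries, where chance gives 16.7% for a single gene. Genes of 1 cell type can move together, so the 12 are not independent trials. The 16.7% is therefore no chance level for their count. The same count was 2 of 6 for Purkinje cells, 1 of them Pcp2, which rests on a count of 1 in cuprizone replicate 1 and so is not shown to be higher there, 3 of 9 for striatal, 1 of 8 for cortical excitatory, 1 of 6 for thalamic and 0 of 5 for olfactory bulb neurons. The 12 granule cell genes summed to 133.04 CPM in cuprizone replicate 1, 956.23 in cuprizone replicate 2, 76.17 in mock replicate 1 and 60.3 in mock replicate 2. For the 8 cortical excitatory genes the sums were 1153.66, 908.55, 1183.79 and 1204.37 CPM in the same order. Cbln3, seen first, had 22.4 and 331 CPM in the cuprizone libraries and Gabra6, a GABA receptor subunit of granule cells, 11.8 and 214, and both had a count of 0 in each mock library.

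The first pattern weighed is the fall of mitochondrially encoded RNA. Less recovery of membrane-bound RNA in the cuprizone pull-downs may contribute: outside the fixed lists, genes whose protein has a predicted membrane or signal segment differed from genes without one by -0.278 in median log2 fold (from -0.331 to -0.191 over the 4 library pairs), against differences of 0.017 within the cuprizone pair and 0.109 within the mock pair. The difference is much smaller than the median of -3.83 of the mitochondrially encoded list and was measured in nuclear genes only. It therefore does not show how mitochondrially encoded RNA was recovered. Of nuclear coding genes with an unadjusted p under 0.05, 79.4% of the lower and 29.9% of the higher ones had such a segment, against 38.3% of all. Camera compares a list with all other genes, so a class difference can enter its calls. Whether it underlies those of the lysosome, ER chaperone, matrix, lipid and MHC class I lists was not tested. More unbound RNA of every compartment, the nucleus included, in the mock pull-downs would lower nuclear RNAs in the cuprizone libraries. The 8 RNAs taken as nuclear all had positive folds, with a median of 1.523, from 1.449 to 1.801 over the pairs. Malat1, Meg3 and Snhg11 among them had prompted the test, so that median restates their rise. The 5 that were not called had 0.853, from 0.396 to 0.944. Of these, Neat1 and Rian had overlapping groups, and Mirg, Miat and Kcnq1ot1 had mean CPMs of 0.841, 2.997 and 4.087. The values therefore cannot decide the question. More unbound RNA from outside the nucleus stays open as untested, since 211 long non-coding RNAs of at least 5 CPM, which were not sorted by compartment, had a median of -0.092, from -0.217 to 0.037 over the pairs. An effect of the diet on mitochondria and on secreted and membrane proteins also stays open as untested, since RNA from before the pull-down was not analysed here. Whether the mitochondrially encoded RNA was bound to tagged ribosomes or carried along unbound was not tested either.

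The second pattern is the lower level of astrocyte genes, Gfap included. A protein class difference of the size seen over all nuclear coding genes does not account for it alone. With the median of each gene's class taken off, the genes of both astrocyte lists still had a median of -0.356. That median ran from -0.577 to -0.204 over the 4 library pairs, and 22 of the genes had a predicted segment and 6 did not. S100b is counted among the 22, although it is known to lack a segment. The class difference was larger within the neuron list, at -0.754 between 7 genes with and 9 without a segment (from -0.937 to -0.479). A class difference of that size among astrocyte genes stays open. A lower share of astrocyte RNA in the cuprizone pull-downs stays open. The median of the 6 members without a predicted segment differed from that of all genes without one by -0.457 on the log2 scale, from -0.659 to -0.284 over the pairs, but these genes belong to the pattern, so the value restates it and does not support a lower share. The members did not move alike, since Gfap, Glul and Aldoc had -1.20, -0.60 and -0.55 while Acsbg1, Aldh1l1 and Sox9 had -0.19, -0.10 and 0.16 with overlapping groups. Fewer astrocytes, lower expression per astrocyte and more RNA from cells outside the target were not tested, and a response of astrocytes to cuprizone stays open.

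The third pattern is the granule cell signal. Cerebellar tissue in the cuprizone samples is a candidate explanation, since 7 of 12 genes listed without sight of their values were higher in both cuprizone libraries. These genes can share 1 difference between libraries, so their number cannot exclude chance. Neurod1, the most abundant of them, had 73.2 and 467 CPM in cuprizone against 38.3 and 29.9 in mock libraries. Of the 12 genes, 8 also had counts in the mock libraries, so the list is not specific to the cerebellum. The signal lay mostly in cuprizone replicate 2, and RNA passed between samples or a change in neurons on the diet was not tested. Protein length also went with the fold: among genes of at least 10 CPM outside the lists, the longest 25% of proteins had a median log2 fold above that of the shortest 25% by 0.417 without and 0.399 with a predicted segment, with pair ranges of 0.124 to 0.72 and 0.129 to 0.607.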
